A study of Mus musculus with 26 samples.

How the data were processed

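Bulk RNA was sequenced from fibroblasts of the ventral skin of Prrx-Cre mice, sorted by FACS into Prrx1-positive (PPF) and Prrx1-negative (PNF) cells, in 24 libraries and 8 groups. The sort gate is not given in the sources used here. Per the labels, skin was minced and digested in collagenase type IV for 60 min at 37 °C, and cDNA was made from a low input of RNA and amplified. Libraries were then made by tagmentation and read as pairs of 75 bases on a HiSeq4000. The amplified cDNA carries no molecular identifiers, so intervals and floors from counts cover counting error only.

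The bulk values are read counts per transcript on mm10, which the authors made with featureCounts, as the deposited tables show, and they are whole numbers as deposited. The FPKM values deposited beside the counts were computed by the authors from the counts and the transcript length, with a total of reads whose definition is not stated, and they were used only to check the counts. Each table lists 95883 transcripts. These were joined to GENCODE vM21, in which 82946 were found, and summed to 34030 genes, 24924 of them with a count. Of the matched transcripts, 83.7% had the same length as in that release, and 5.253% of counts fell in the 12937 transcripts that were not found and were left out. Reads that overlap several transcripts appear not to have been counted. Transcripts with at least 50% of bases of their own made up 37.13% of transcripts and held 91.213% of counts, and transcripts with 0 such bases made up 22.55% and held 0.279%. The counts came to between 9.558% (PNF E18.5 A) and 17.078% (PPF P1 B) of the reads implied by the FPKM values. Gene levels here are therefore levels of the parts of genes that a single transcript covers, which is a limit on comparing genes with each other and on genes with many isoforms.

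Libraries held 4264657 to 17190154 counts in genes. Genes were filtered with edgeR's filterByExpr, which left 15559, and scaled by TMM with factors of 0.654 to 1.298. A quasi-likelihood fit in edgeR 4.0.16 (R 4.3.3) took each of the 8 groups as a term, with 16 residual degrees of freedom, a prior of 5.06 and a common biological coefficient of variation of 1.029. Contrasts compared PPF with PNF at each age and averaged over the 4 ages with equal weight, E18.5 and P30 with E16.5 within each lineage, and the change from E16.5 to P30 between lineages. An F test took the interaction of lineage and age. Tests are two-sided, and p-values were adjusted over all tested genes by the method of Benjamini and Hochberg with a threshold of 0.05. On simulated data with the spread of these libraries and 200 changed genes, 0 changed 4-fold were recovered at E16.5 and at P30, and 68 in the average.

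The comparisons, alternatives, gene lists and rule for naming genes were fixed before the data were examined. The rule names up to 8 genes per direction with the largest change among those past the threshold. These have a mean of at least 10 CPM in the higher group and no overlap between libraries of the groups (at any age, for the average), and predicted, pseudogene, antisense, microRNA and clone names and sex-linked genes are left out. It also names up to 4 genes per list with the smallest p, called or not, the 5 leading genes of each single-cell cluster, and Prrx1 always. In total 43 gene lists were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether the genes of a list move one way. For genes with 0 counts over a group, the fold is a lower bound from a floor of 3 counts.

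Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, no filter on low counts, a filter at 1 CPM, RLE and upper quartile scaling, a threshold on the fold (glmTreat), libraries A and B only, a replicate block, a fit of only the groups compared, and each library left out in turn. Scaling moved the median log2 fold change of all genes from -0.31 to -0.17 (RLE) and -0.21 (upper quartile) at E18.5, from -0.24 to -0.52 (RLE) at P1 and from 0.38 to 0.24 (upper quartile) at P30. From E16.5 to P30 it moved from 0.15 to 0.46 (RLE) and 0.09 (upper quartile) in PPF, where the split of calls was 40 higher and 66 lower with RLE in place of 28 and 85, and from -0.29 to 0.02 (RLE) in PNF. From E16.5 to P30 in PPF the split was 712 higher and 264 lower with DESeq2 and 56 and 29 in the fit of only the groups compared. Further alternatives were chosen after seeing the data: leaving out 2 libraries rich in erythroid RNA, summing libraries C and D and libraries E and F of a group, fitting only genes with a count in every group, and leaving members of any other cell type list out of the genes located in the single cells. In contrasts over more than 2 groups, a group at 0 counts can absorb the tested difference at no cost to the fit, so that some such genes cannot be called in the edgeR average or difference of changes.

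The single-cell values are UMI counts per gene and barcode, made by the authors with the software of the 10x platform (version 3.1.0 per the file headers), with barcodes already selected as deposited. The submitters name Seurat 3.2 and 3.1.1 for later steps, which were not used here. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 18374 of 27519 barcodes in tube 1 and 4779 of 5567 in tube 2. With scanpy 1.11.5 (Python 3.11.15), counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 components and 15 neighbours were used for Leiden clusters (leidenalg 0.10.2, resolution 0.5). A list of another cell type passed in a cluster when at least 3 of its markers had 0.5 UMIs per 10000 and stood at least 2-fold above the other clusters, with a mean log2 fold of at least 1 over the list. A cluster was named for that type when only 1 list passed and the list held a gene among the 5 leading genes of the cluster or 3 genes among the 10 leading by fold. With several lists passing, or 1 passing without such leading genes, it was left unnamed. It was fibroblast-like when no list passed and at least 8 of 10 fibroblast markers were detected, which held in every cluster and so decided nothing. That naming rule was set after the clusters were seen. Scrublet predicted 0 doublets in both tubes, which is no evidence that there were none, since 1.263% and 0.9625% of cells carried 2 hashtags. The levels of genes called in bulk were compared with 10000 random lists of the same size and similar summed UMIs in the tube. Each gene of a random list was drawn by itself. Called genes of 1 cell type are not independent, so the percentiles are descriptive. Hashtag counts were not used to group cells.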

Results

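Bulk RNA sequencing covered fibroblasts sorted from the ventral skin of Prrx-Cre mice, in which cells with a history of the mesenchymal transcription factor Prrx1 are told apart from cells without it. The Prrx1-positive fibroblasts are called PPF and the Prrx1-negative fibroblasts PNF. Both were taken at the embryonic ages E16.5 and E18.5 and the postnatal ages P1 and P30. PPF had 2 libraries at E16.5, E18.5 and P1 and 6 at P30. PNF had 2 libraries at E16.5, 4 at E18.5, 4 at P1 and 2 at P30, which makes 24 libraries in 8 groups. Counts assigned to genes per library were 6860824 and 8862896 in PNF and 6111708 and 6603613 in PPF at E16.5. At E18.5 they were 5608500 to 9008313 in PNF and 5149715 and 5417922 in PPF, and at P1 5843938 to 16792015 in PNF and 5724921 and 9429563 in PPF. At P30 they were 4264657 and 17190154 in PNF and 4591721 to 12042400 in PPF. Between 6508 genes (PNF P30 A) and 19421 genes (PNF P1 B) had at least 1 count. Levels below are CPM, counts relative to the scaled library total, given as mean ± SD over libraries, and positions are on mm10. Adjusted p-values of genes are from edgeR. The p-values measure the spread between libraries, and the labels do not say whether the libraries of a group come from separate animals.

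Prrx1 itself (ENSMUSG00000026586, chromosome 1, 163245119 to 163313710), the homeobox gene that names the lineages, had transcripts in both. Its level at E16.5 was 46.7 ± 6.98 CPM in PPF and 37.4 ± 6.43 CPM in PNF (n = 2 each). At E18.5 it was 91.3 ± 8.44 CPM (n = 2) against 57.9 ± 31.2 CPM (n = 4), and at P1 50.2 ± 10.4 CPM (n = 2) against 37.0 ± 7.95 CPM (n = 4). At P30 it was 68.4 ± 48.4 CPM (n = 6) against 30.4 ± 43.0 CPM (n = 2), the latter being the mean of 0 in PNF P30 A and 60.8 CPM in PNF P30 B. The PPF mean was the higher at each of the 4 ages, and the difference averaged over them did not pass the edgeR test (adjusted p = 0.694, 1.53-fold between plain means over all libraries).

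The first question was which genes differ between the lineages whatever the age. Averaged over the 4 ages, several transcription factors of body position and mesenchyme were higher in PPF (n = 12) than in PNF (n = 12). Only the test gives each age the same weight. Levels and folds are plain means over the libraries, of which P30 made up 6 in PPF and 2 in PNF. The eye and ventral patterning homeobox gene Vax2 (ENSMUSG00000034777, chromosome 6, 83711264 to 83738313) was 7.94-fold higher (79.5 ± 66.8 against 10.0 ± 8.71 CPM), with an adjusted p of 0.0412 in edgeR. The posterior HOX gene Hoxc9 (ENSMUSG00000036139, chromosome 15, 102976439 to 102985099) was 3.54-fold higher (50.0 ± 22 against 14.1 ± 4.92 CPM, adjusted p = 0.0189). Osr2 (ENSMUSG00000022330, chromosome 15, 35296098 to 35303305), a zinc finger factor of limb mesenchyme, was 3.03-fold higher (724 ± 538 against 239 ± 105 CPM, adjusted p = 0.0406). The PPF libraries lay above the PNF libraries within every age for these 3 genes. Tox (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557), an HMG-box regulator known from T cells, was 7.33-fold lower in PPF (2.41 ± 3.50 against 17.6 ± 14.9 CPM, adjusted p = 0.0312), again with no overlap at any age.

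Some of the other genes higher in PPF belong to positional gene lists that were fixed beforehand. In the posterior HOX list (groups 9 to 13), 2 of 15 tested genes rose, Hoxc9 and Hoxc10 (45.8 ± 29.8 against 14 ± 17.6 CPM, adjusted p = 0.0333), and 13 did not pass, while 4 rose when adjusted over the list alone. The somite and dorsal list had 1 gene up, En1, a homeobox factor of trunk dermis (36.2 ± 11.3 against 10.5 ± 6.37 CPM, adjusted p = 0.0204), and 1 down, the muscle determination factor Myf5 (0.235 ± 0.778 against 9.86 ± 9.27 CPM, adjusted p = 0.0347), of 17. In the limb and lateral plate list 2 of 24 rose, Osr2 and the dermal bHLH factor Twist2 (487 ± 362 against 234 ± 122 CPM, adjusted p = 0.0464). The YAP and mechanical response list split, with the matricellular gene Ccn1 2.16-fold higher (7990 ± 3277 against 3694 ± 1033 CPM, adjusted p = 0.0122) and Ankrd1 30-fold lower (0.303 ± 0.639 against 9.11 ± 20.8 CPM, adjusted p = 0.0308) among 18. In the list of collagens and fibrillar matrix, Fbln1 rose (383 ± 202 against 194 ± 81.0 CPM, adjusted p = 0.0384) and 23 of 24 genes did not pass, Col5a1 standing at 6408 ± 3850 against 2859 ± 1428 CPM (adjusted p = 0.0831). Adjusted over the list alone, 5 matrix genes were higher and 1 lower. In the list of TGF-beta signalling 0 of 21 and in the contractile and myofibroblast list 0 of 19 passed. In the papillary fibroblast list 0 of 15 passed, with Crabp1 at 1618 ± 957 against 650 ± 512 CPM (adjusted p = 0.0571), while 5 were higher and 1 lower when adjusted over the list alone. Camera, which ranks a list against all other genes, placed the matrix list upward (median log2 fold change 0.70, adjusted p = 2.74e-05, and adjusted p = 0.283 with an estimated correlation) and the papillary list upward (0.56, adjusted p = 0.000647, and adjusted p = 0.139 with an estimated correlation). It also placed the anterior HOX list (0.73, adjusted p = 0.000539) and the posterior HOX list (adjusted p = 0.0178) upward, with adjusted p = 0.147 and adjusted p = 0.283 with an estimated correlation. The median of the posterior HOX list was -0.04 and so opposite in sign to its test.

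Most of the genes that differed were lower in PPF, and many are markers of cells other than fibroblasts. Of the mast cell list, 4 of 7 tested genes fell, among them the proteases Cpa3 (57.8 ± 142 against 1209 ± 1133 CPM, adjusted p = 0.000138) and Tpsb2 (22.4 ± 65.0 against 238 ± 222 CPM, adjusted p = 0.000261). Of the keratinocyte list 7 of 16 fell, among them the basal keratins Krt15 (10.3 ± 15.8 against 179 ± 193 CPM, adjusted p = 0.00493) and Krt5 (36.6 ± 61.5 against 208 ± 254 CPM, adjusted p = 0.00814). Of the Schwann and neural list 4 of 12 fell, led by the neural crest factor Sox10 (0.0756 ± 0.214 against 2.78 ± 1.62 CPM, adjusted p = 0.0105). Of the skeletal muscle list 3 of 12 fell, including Acta1 (13.1 ± 21.7 against 157 ± 186 CPM, adjusted p = 0.0412). Of the macrophage and dendritic list 3 of 12 fell, including Lyz2 (20.9 ± 24.9 against 404 ± 674 CPM, adjusted p = 0.041), and of the neutrophil list 2 of 7, including S100a8 (9.86 ± 12.1 against 533 ± 732 CPM, adjusted p = 0.00229). Adjusted over each list alone, 7 mast cell, 15 keratinocyte, 8 Schwann, 9 muscle, 8 macrophage and 5 neutrophil genes were lower. Camera ranked the mast cell list downward (median log2 fold change -6.35, adjusted p = 5.96e-18). It ranked the keratinocyte list downward too (median -5.25, adjusted p = 3.69e-15). The first call was kept (adjusted p = 0.00526 with an estimated correlation) and the second was not (adjusted p = 0.0645 with an estimated correlation). Hdc stands in both the mast cell and the neutrophil list, Myf5 in both the somite and the muscle list, and Sox10 in both the Schwann and the melanocyte list.

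In all, edgeR placed 105 of 15559 tested genes past an adjusted p of 0.05 in the average, 13 higher and 92 lower in PPF, with 2164 at an unadjusted p under 0.05. The levels above are plain means over 12 libraries, whereas the test gives each age the same weight. DESeq2 on the same genes called 844 (127 higher and 717 lower) and limma voom 782 (137 and 645). Of the 92 lower genes, 82 had 0 counts in at least 1 of the 8 groups, and of the 13 higher genes none did. The 11250 genes with a count in every group held 13 higher and 10 lower calls in edgeR, 120 and 147 in DESeq2 and 129 and 150 in limma voom. The genes with a group at 0 held 7 higher and 570 lower calls in DESeq2 and 8 and 495 in limma voom. A group at 0 counts also kept 1088 genes from being called in the edgeR average (F under 0.001), 464 of them with the higher mean log2(CPM + 1) in PPF and 624 with the lower. A fit of only the genes with a count in every group, chosen after the data were seen, left 0 higher and 1 lower gene, so that Vax2, Hoxc9, Osr2, Hoxc10, En1, Twist2, Ccn1 and Fbln1 did not pass in it. The count rested on few libraries. It was 2 without PPF P1 A, 2 without PPF P1 B, 3 without PPF E16.5 A, 14 without PPF E16.5 B, 13 without PPF E18.5 A and 12 without PPF E18.5 B. It was 47 without PNF E16.5 A and 49 without PNF E16.5 B. It was 66 without PNF E18.5 D, 218 without PNF P30 A and 1480 without PNF P30 B, where most were higher in PPF (1273 higher and 207 lower). Of the genes named above, Cpa3 and Tpsb2 stayed past the threshold in each of the 24 fits that left out 1 library (highest adjusted p = 0.0162 for both, without PPF P1 B). Ccn1 kept its call in 18 of 24, Hoxc9, En1 and Tox in 16, Ankrd1 in 15, Hoxc10 in 14, Fbln1, Myf5 and Lyz2 in 12, Osr2 and Acta1 in 10, Vax2 in 8 and Twist2 in 3. PNF E18.5 A and PNF P30 A had 43.2% and 46.6% of counts in the erythroid list, and leaving out both gave 320 genes. Summing the closely similar libraries C and D and libraries E and F of a group gave 50, 0 higher and 50 lower, so none of the 13 genes higher in PPF kept its call. PNF E16.5 A and B were as alike (Pearson r of log2 CPM 0.965, against 0.872 to 0.962 in the summed pairs) and were kept apart. Both alternatives were chosen after the data were seen.

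**Figure D1:**
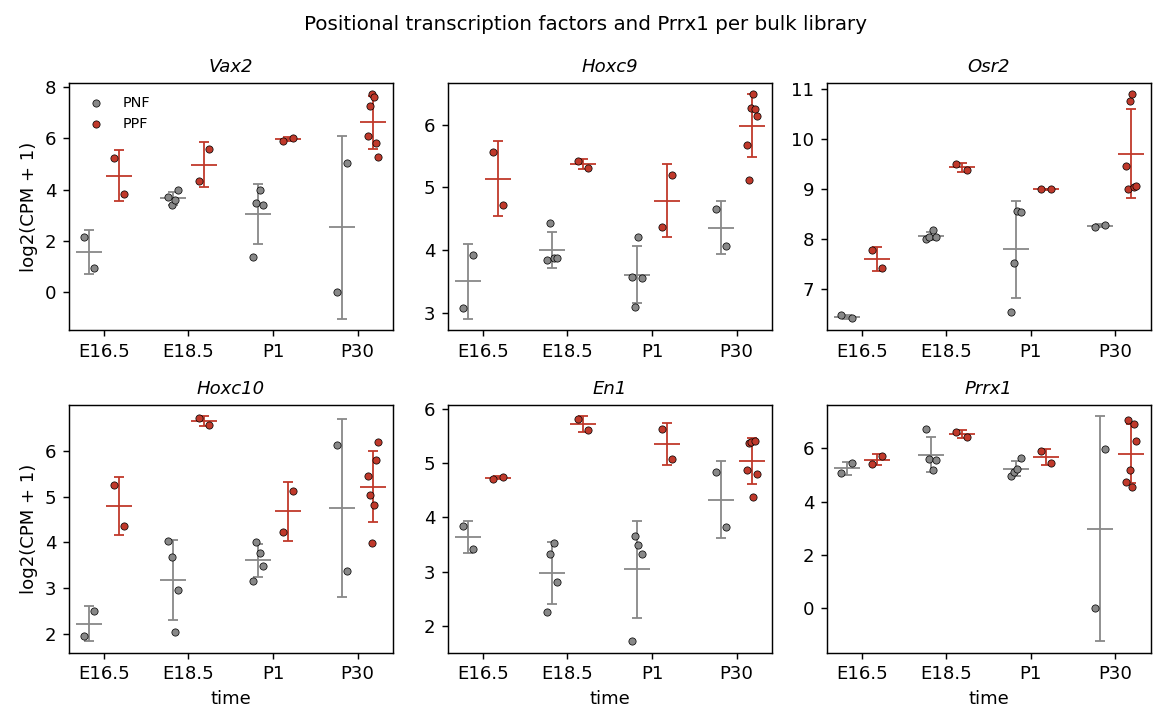
Levels of positional transcription factors and Prrx1 by age, as log2(CPM + 1), with a point per library, a dash at the group mean and bars of 1 SD of the log2 values. As plain means over all libraries of a lineage, Hoxc9 had 50.0 CPM in PPF and 14.1 CPM in PNF.

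**Figure D2:**
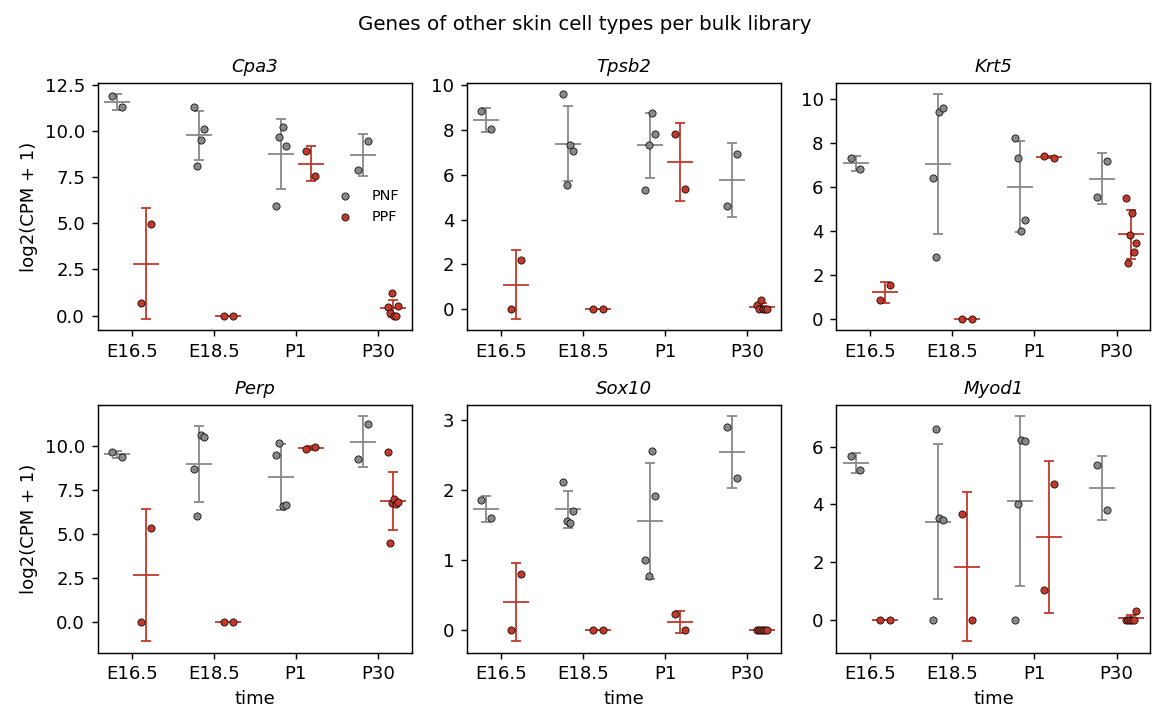
Levels of markers of other skin cell types by age, as log2(CPM + 1), with a point per library, a dash at the group mean and bars of 1 SD of the log2 values. Cpa3 had 1209 CPM in PNF and 57.8 CPM in PPF over 12 libraries each.

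At E16.5 the lineages, with 2 libraries each, differed in the mean levels of mast cell and keratinocyte genes, and no gene passed the test. Cpa3 had 15.2 ± 20.6 CPM in PPF and 3128 ± 899 CPM in PNF, and the histamine enzyme Hdc 8.35 ± 6.55 against 664 ± 279 CPM. Krtdap, a gene of differentiating keratinocytes, had 25.9 ± 1.30 against 1372 ± 180 CPM. In the other direction, Hoxc10 had 28.2 ± 12.5 against 3.72 ± 1.24 CPM and Hoxb9 46.1 ± 16.0 against 8.31 ± 0.299 CPM, with Hoxc9 at 35.8 ± 14.9 against 10.8 ± 4.78 CPM. Adjusted over the list alone, 6 of 7 mast cell and 8 of 16 keratinocyte genes were lower in PPF. The mast cell list ranked downward in camera (median log2 fold change -7.63, or -7.46 with genes at 0 in a group set to their bound, adjusted p = 7.47e-21), which held at adjusted p = 0.00241 with an estimated correlation. Camera also placed the keratinocyte list down (adjusted p = 1.07e-15) and the posterior HOX list up (adjusted p = 2.4e-06), each with adjusted p = 0.0572 with an estimated correlation.

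By edgeR 0 of the 15559 genes passed at E16.5, where the smallest adjusted p was 1 and 313 genes had an unadjusted p under 0.05, while DESeq2 called 89 and limma voom 116. Tested on simulated data with the spread of these libraries, edgeR recovered 0 of 200 genes changed 4-fold and 37 of 200 changed 16-fold in this comparison.

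At E18.5 the PPF libraries (n = 2) held no counts at all of many genes that PNF libraries (n = 4) expressed, and Ccn1 was the gene that rose in edgeR. Ccn1 (ENSMUSG00000028195, chromosome 3, 145646976 to 145649981) had 11490 ± 984 CPM in PPF and 3180 ± 280 CPM in PNF, 3.61-fold more (adjusted p = 0.0482). Folds against a group with 0 counts are lower bounds from a floor of 3 counts over the group. Cpa3 was at least 5280-fold lower in PPF (1169 ± 978 CPM in PNF, adjusted p = 0.0118) and Krt5 at least 1730-fold (384 ± 394 CPM in PNF, adjusted p = 0.0301). Trim29, an epithelial gene, was at least 1270-fold lower (281 ± 288 CPM in PNF, adjusted p = 0.0482). The stem cell antigen gene Ly6a, which marks fascia and reticular fibroblasts, was at least 882-fold lower (195 ± 80.9 CPM in PNF, adjusted p = 0.028), and Mfap5, a microfibril gene, at least 222-fold (49.1 ± 33.5 CPM in PNF, adjusted p = 0.041). Moxd1 was at least 804-fold lower (178 ± 69.9 CPM in PNF, adjusted p = 0.0301) and the cytokine gene Il6 at least 179-fold (39.7 ± 52.3 CPM in PNF, adjusted p = 0.0251).

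By list, 3 of 16 keratinocyte and 3 of 7 mast cell genes fell at E18.5, and every tested member of both lists was lower when adjusted over the list alone. The keratinocyte list had a median log2 fold change of -10.64 (-9.11 with genes at 0 set to their bound), which camera placed down at adjusted p = 1.46e-14, and at adjusted p = 0.0927 with an estimated correlation. In the reticular and fascia list 2 of 16 fell, Ly6a and Mfap5, and 14 did not pass (camera adjusted p = 0.0055, and adjusted p = 0.547 with an estimated correlation). The matrix list had 0 of 24 genes past the test, Fbln1 standing at 772 ± 54.8 against 213 ± 62.2 CPM (adjusted p = 0.057). Hoxc10 had 99.2 ± 7.34 against 9.25 ± 5.37 CPM (adjusted p = 0.065) and En1 52.0 ± 5.18 against 7.31 ± 3 CPM (adjusted p = 0.0713), and their PPF and PNF libraries did not overlap.

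In all, edgeR called 28 genes at E18.5, 1 higher and 27 lower, 23 of them with 0 counts in both PPF libraries. DESeq2 called 1128 (147 higher and 981 lower) and limma voom 683 (346 and 337). None of the 28 genes, Cpa3, Krt5, Trim29, Ly6a, Mfap5, Moxd1 and Il6 among them, kept its call without PPF E18.5 A or without PPF E18.5 B, which gave 2 and 5 other genes. The count was 50 without PNF E18.5 A, 14 without PNF E18.5 C and 13 without PNF E18.5 D. Ccn1 kept its call in 0 of the 6 fits that left out 1 library (highest adjusted p = 0.356, without PPF E18.5 B). Without the 2 libraries rich in erythroid RNA it was 218, and with the similar libraries summed 6.

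At P1 several keratinocyte genes stood the other way round, with a higher mean in PPF (n = 2) than in PNF (n = 4), though no gene passed the test. The suprabasal keratins Krt1 and Krt10 had 2223 ± 953 against 55.4 ± 76.6 CPM and 842 ± 156 against 40.6 ± 22 CPM, and Krtdap 1096 ± 373 against 88.7 ± 143 CPM. En1 had 40.7 ± 11.2 against 8.26 ± 4.12 CPM and Hoxb9 65.3 ± 17.1 against 12.1 ± 2.99 CPM. The tendon gene Thbs4 had 15.6 ± 6.95 against 520 ± 440 CPM and Acta1 39.8 ± 46.7 against 320 ± 261 CPM. The keratinocyte list took 0.914% and 0.842% of counts in PPF P1 A and B, and 0.041% to 0.623% in the PNF libraries. Libraries overlapped for Krt5 (169 and 161.5 CPM in PPF, 297.9 CPM in PNF P1 A). They also overlapped for Perp (886.7 and 978.3 CPM in PPF, 1136 CPM in PNF P1 B). Adjusted over the list alone, 4 of 16 keratinocyte genes were higher in PPF. Camera placed that list up (median log2 fold change 0.48, adjusted p = 0.00105) and the skeletal muscle list down (adjusted p = 0.00105). The median of the latter was -2.85, or -2.49 with genes at 0 set to their bound. Neither held, at adjusted p = 0.548 with an estimated correlation for each. Against En1 and Hoxb9, camera placed the posterior HOX list down at P1 (10 of 15 genes negative, median -4.231, or -3.605 with genes at 0 set to their bound, adjusted p = 0.0274). It placed the somite and dorsal list down too (15 of 17 negative, median -2.035, adjusted p = 0.0205), and both were at adjusted p = 0.548 with an estimated correlation. Counts by edgeR were 0 of 15559 genes past the threshold (smallest adjusted p = 0.959) and 615 with an unadjusted p under 0.05, while DESeq2 called 49 and limma voom 293. Lor, a keratinocyte list member at 559 ± 774 against 18.1 ± 4.86 CPM, changed its direction to a log2 fold change of -0.67 without PPF P1 A.

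At P30 the phospholipid phosphatase gene Plpp3 (ENSMUSG00000028517, chromosome 4, 105157347 to 105232764) was higher in PPF (3367 ± 753 CPM, n = 6) than in PNF (966 ± 284 CPM, n = 2), 3.49-fold (adjusted p = 0.0423). Cpa3 was 1260-fold lower in PPF (0.377 ± 0.502 against 474 ± 340 CPM, adjusted p = 0.000612), and Tpsb2 had 2 counts over the 6 PPF libraries against 72.5 ± 69.4 CPM in PNF (adjusted p = 0.00201). The granule genes Ltf and Ctsg of myeloid cells were at least 5290-fold and at least 475-fold lower (383 ± 499 and 34.4 ± 41.4 CPM in PNF, adjusted p = 0.0388 and 0.0423). The cardiac and fetal muscle actin gene Actc1 was at least 2080-fold lower (151 ± 144 CPM in PNF, adjusted p = 0.0388). Krt79 was 280-fold lower (0.909 ± 1.73 against 255 ± 360 CPM, adjusted p = 0.0423) and Sox10 at least 68.9-fold (4.99 ± 2.09 CPM in PNF, adjusted p = 0.0423).

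By list, 2 of 7 mast cell, 1 of 16 keratinocyte, 1 of 12 Schwann and 1 of 7 neutrophil genes fell at P30, and 6, 7, 4 and 3 of them when adjusted over the list alone. None of the 16 reticular and fascia genes passed, with Gpx3, a secreted glutathione peroxidase, at 8241 ± 8222 against 499 ± 527 CPM (adjusted p = 0.129) and Cd248 at 3351 ± 3478 against 506 ± 247 CPM (adjusted p = 0.312). Camera placed that list up (median log2 fold change 2.34, adjusted p = 2.56e-05, and adjusted p = 0.322 with an estimated correlation). The matrix list also had 0 of 24 genes past the test (median 1.11, camera adjusted p = 0.00899, and adjusted p = 0.603 with an estimated correlation). Erythroid genes took 46.6% of counts in PNF P30 A and 0.133% in PNF P30 B, the latter within the range of 0.027% to 1.76% in PPF.

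In all, edgeR called 19 genes at P30, 1 higher and 18 lower, 6 of them at 0 counts in every PPF library, while DESeq2 called 230 (94 higher and 136 lower) and limma voom 34 (1 and 33). There were only 2 PNF libraries, 1 of them rich in erythroid RNA, so leaving out either leaves 1 library to stand for PNF. The median log2 fold change of all genes was 0.38 with both, 4.44 without PNF P30 B and 0 without PNF P30 A. The count of calls was 31 without PPF P30 A, 5 without B, 3 without C, 3 without D, 6 without E and 3 without F of PPF P30. Krt79 changed its direction to a log2 fold change of 5.99 without PNF P30 B. Plpp3, Ltf, Ctsg, Actc1, Krt79 and Sox10 each kept the call in 2 of 8 such fits, and Cpa3 and Tpsb2 kept theirs in 8 of 8. Without the 2 libraries rich in erythroid RNA the count was 6, and with the similar libraries summed 1.

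**Figure D3:**
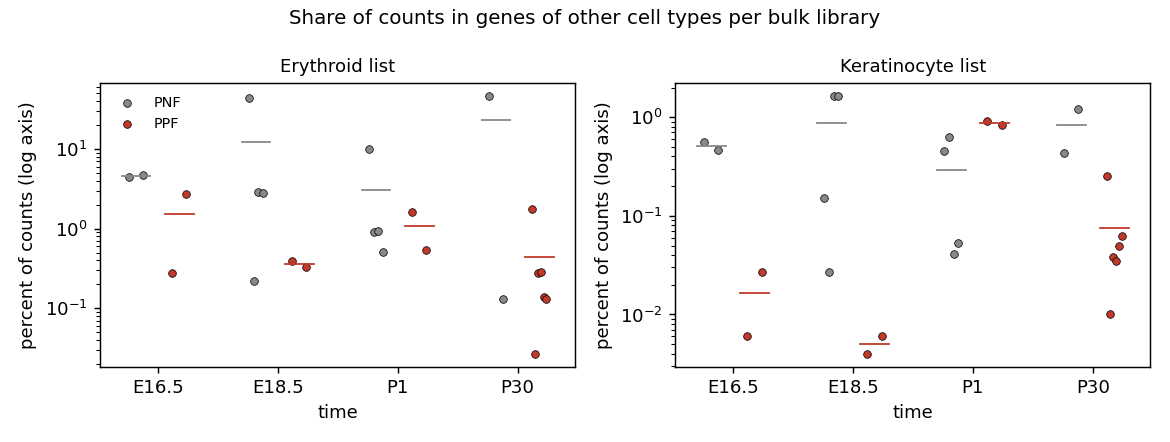
Share of counts in the erythroid and keratinocyte lists per library, in percent on a log axis, with a point per library and a line at the group mean. The erythroid share reached 46.6% in PNF P30 A and 43.2% in PNF E18.5 A.

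Whether the lineage difference depends on age was tested with the interaction of lineage and age. Camera ranked the mast cell list downward at E16.5, E18.5 and P30, with adjusted p = 0.00241, adjusted p = 0.0623 and adjusted p = 0.153 with an estimated correlation. Cpa3 and Tpsb2 were the 2 genes called lower at both E18.5 and P30 (0.0312 expected for unrelated calls). Keratinocyte genes such as Krt1 stood lower in PPF at E16.5 and higher at P1. Log2 fold changes across the 15559 genes had Pearson r (Spearman rho) of 0.298 (0.158) between E16.5 and E18.5, 0.265 (0.213) between E16.5 and P30 and 0.184 (0.091) between E18.5 and P30. Pairs with P1 gave 0.124 (0.143) with E16.5, 0.132 (0.101) with E18.5 and -0.009 (-0.011) with P30. These 6 values are across genes, which are not independent replicates, so no p is given. In edgeR 0 genes passed the interaction test (smallest adjusted p = 0.0606, 1038 genes with an unadjusted p under 0.05), while DESeq2 called 172 and limma voom 699. The count was 1453 without PNF P30 B, 15 without PNF P30 A, 9 without PNF E18.5 B, 9 without PPF P30 A, 7 without PNF E18.5 A, 4 without PNF P1 B, and 1 without each of PPF E16.5 A, PPF E16.5 B, PPF E18.5 B and PNF P1 A. It was 39 without both libraries rich in erythroid RNA.

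Within PPF, the time course asked how the lineage changes from fetal to postnatal skin. Between E16.5 and E18.5 (n = 2 each), Ly6a went from 466 ± 151 CPM to 0 counts, at least 2100-fold lower (adjusted p = 0.0401). Il6 fell at least 147-fold from 32.6 ± 27.9 CPM (adjusted p = 0.0467) and the pterin enzyme gene Pts at least 334-fold from 73.9 ± 1.29 CPM (adjusted p = 0.0263). The musculoskeletal gene Mustn1 fell at least 210-fold from 46.6 ± 11.2 CPM (adjusted p = 0.0401) and Qpctl at least 147-fold from 32.5 ± 4.28 CPM (adjusted p = 0.00372). In the reticular and fascia list 1 of 16 fell, and 8 when adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.833 with an estimated correlation). In the tendon list 0 of 9 passed by edgeR, and 6 were lower when adjusted over the list alone, Thbs4 standing at 0 counts against 78.2 ± 4.85 CPM (adjusted p = 0.0699). By edgeR 9 genes passed, 0 higher and 9 lower, with 1907 at an unadjusted p under 0.05, and 652 by DESeq2 (177 higher and 475 lower) and 37 by limma voom (17 and 20). All 9 were also among the genes lower in PPF than in PNF at E18.5, a comparison that shares the PPF E18.5 libraries, and 8 of the 9 had 0 counts in both of these. Ly6a, Il6 and Mustn1 kept their calls in 0 of the 4 fits that left out 1 library, and Pts and Qpctl in 2. The count was 3 without PPF E16.5 A, 3 without PPF E16.5 B, 0 without PPF E18.5 A and 3 without PPF E18.5 B, the latter 3 not among the 9. It was 164 without both libraries rich in erythroid RNA and 1 with the similar libraries summed.

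From E16.5 (n = 2) to P30 (n = 6) in PPF, Gpx3 rose 108-fold (76.1 ± 17.2 to 8241 ± 8222 CPM, adjusted p = 0.0202) and the cytokine signalling inhibitor Socs3 20.7-fold (91.8 ± 51.7 to 1903 ± 839 CPM, adjusted p = 0.0107). The adhesion receptor Icam1 rose 11.7-fold (108 ± 1.74 to 1268 ± 467 CPM, adjusted p = 0.0273) and the complement inhibitor Serping1 31.2-fold (65.2 ± 6.39 to 2034 ± 1126 CPM, adjusted p = 0.0255). Cyp2f2, a cytochrome P450 gene, rose at least 4430-fold to 1144 ± 916 CPM (adjusted p = 0.0255). Igf2bp3, a fetal mRNA-binding protein gene, fell 48.1-fold (52.5 ± 21.9 to 1.09 ± 1.37 CPM, adjusted p = 0.0107), and the imprinted factor Plagl1 13.8-fold (834 ± 274 to 60.6 ± 40.5 CPM, adjusted p = 0.015). The chromatin gene Hmgb2 fell 9.60-fold (1675 ± 340 to 174 ± 125 CPM, adjusted p = 0.015) and the hindlimb factor Pitx1 at least 309-fold from 22.4 ± 17.0 CPM (adjusted p = 0.0255).

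By list, the proliferation list had 2 of 25 genes that fell from E16.5 to P30 in PPF, Hmgb2 and Tk1 (61.9 ± 35.3 to 9.66 ± 4.87 CPM, adjusted p = 0.0407). When adjusted over the list alone 17 fell, with Mki67 at 95.5 ± 21.4 and 7.44 ± 5.04 CPM (adjusted p = 0.0531). Camera placed it down (median log2 fold change -3.26, adjusted p = 5.68e-18, and adjusted p = 0.0487 with an estimated correlation). The imprinted and fetal growth list had 2 of 20 that fell and 9 when adjusted over the list alone (camera adjusted p = 1.71e-09, and adjusted p = 0.121 with an estimated correlation). The list of immediate early and dissociation stress genes, which handling of the tissue can raise too, had 3 of 22 that rose, Socs3, Junb (980 ± 213 to 6853 ± 2955 CPM, adjusted p = 0.0255) and Zfp36 (271 ± 138 to 2708 ± 1776 CPM, adjusted p = 0.0338). When adjusted over the list alone 12 were higher and 1 lower (camera adjusted p = 1.44e-09, and adjusted p = 0.171 with an estimated correlation). The interferon and MHC class I list had 1 of 22 that rose, B2m (631 ± 177 to 3069 ± 491 CPM, adjusted p = 0.0255). When adjusted over the list alone 4 rose (camera adjusted p = 4.36e-09, and adjusted p = 0.13 with an estimated correlation). The complement list had 1 of 11 that rose, Serping1, and the chemokine and cytokine list 2 of 22, Icam1 and Nfkbia (659 ± 288 to 2722 ± 567 CPM, adjusted p = 0.0255). Lists of other cell types ranked upward as well. The melanocyte list had 1 of 7 that rose, Gpnmb (0.517 ± 0.730 to 333 ± 167 CPM, adjusted p = 0.0255), and a median log2 fold change of 4.644 (camera adjusted p = 0.00016, and adjusted p = 0.171 with an estimated correlation). In the keratinocyte list 0 of 16 passed, with a median of 3.699, or 2.995 with genes at 0 set to their bound (camera adjusted p = 0.00396, and adjusted p = 0.605 with an estimated correlation). In the cartilage and bone list 4 of 14 fell, among them the bone matrix gene Ibsp (129 ± 158 CPM to 1 count over 6 libraries, adjusted p = 0.00718), Col9a2 (2068 ± 2885 to 9.48 ± 5.03 CPM, adjusted p = 0.0365) and Sox9 (298 ± 320 to 35.1 ± 18.9 CPM, adjusted p = 0.0337). The median log2 fold change of that list was -5.25 (-4.78 with genes at 0 set to their bound, camera adjusted p = 3.25e-05, and adjusted p = 0.228 with an estimated correlation). It was -0.10 with 0 genes past the test without PPF E16.5 B, and -6.25 with 1 gene without PPF E16.5 A.

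In all, edgeR called 113 genes between E16.5 and P30 in PPF, 28 higher and 85 lower, while DESeq2 called 976 (712 higher and 264 lower) and limma voom 1141 (334 and 807). A fit of only the groups compared called 85, of which 56 were higher and 29 lower and 36 were among the 113. Which genes are called, and the balance of higher and lower calls, therefore depend on the fit. The count was 5 without PPF E16.5 A, 0 without PPF E16.5 B, and 41, 32, 25 and 17 without C, D, E and F of PPF P30, so each call was lost without at least 1 library. It was 411 without both libraries rich in erythroid RNA and 0 with the similar libraries summed.

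In PNF no gene passed in either time comparison, although several lists leaned the same way as in PPF. From E16.5 (n = 2) to E18.5 (n = 4), Ibsp had 135 ± 31.9 and 12.9 ± 10.1 CPM and the type IV collagen gene Col4a1 710 ± 71.3 and 1469 ± 202 CPM. Camera placed the cartilage and bone list down (median log2 fold change -0.99, adjusted p = 4.79e-08) and the basement membrane list up (1.05, adjusted p = 3.53e-05). These were adjusted p = 0.477 and adjusted p = 0.486 with an estimated correlation. From E16.5 to P30 (n = 2 each), Socs3 had 98.6 ± 26.5 and 950 ± 681 CPM, Hmgb2 1629 ± 10.4 and 296 ± 219 CPM and Igf2bp3 78.4 ± 13.4 and 6.48 ± 1.43 CPM. Camera placed the proliferation list (median log2 fold change -2.16, adjusted p = 0.000109) and the imprinted list (-1.93, adjusted p = 0.000148) down and the interferon list up (2.68, or 1.92 with genes at 0 set to their bound, adjusted p = 3.58e-06), with adjusted p = 0.517 with an estimated correlation for each. The cartilage and bone list had a median of -5.184, or -4.14 with genes at 0 set to their bound, with 0 of 14 genes past the test (camera adjusted p = 6.82e-05, and adjusted p = 0.517 with an estimated correlation). By edgeR 0 genes passed between E16.5 and E18.5 (331 at an unadjusted p under 0.05, 17 by DESeq2, 2350 by limma voom) and 0 between E16.5 and P30 (837 at an unadjusted p under 0.05, 117 by DESeq2, 459 by limma voom). The latter count was 1693 without PNF P30 B, 3 without PNF P30 A and 13 without both libraries rich in erythroid RNA.

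The change from E16.5 to P30 was not shown to differ between the lineages. The proliferation list had a median difference in log2 change, PPF minus PNF, of -1.10 (camera adjusted p = 0.000502, and adjusted p = 0.929 with an estimated correlation). In edgeR 0 genes passed that test (374 at an unadjusted p under 0.05), while DESeq2 called 58 and limma voom 3, and the edgeR count was 1714 without PNF P30 B.

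Single-cell sequencing covered PPF and PNF from caudal and ventral skin, unwounded and wounded, pooled with hashtags into 2 tubes. Which hashtag marks which sample is not given in the sources used here. Each tube is therefore described by itself and no comparison of groups was made. After filtering, tube 1 held 18374 cells (median 2719 UMIs and 1209 genes per cell) and tube 2 held 4779 cells (median 4462 UMIs and 1698 genes). Clusters in which no list of another cell type passed are called fibroblast-like here. At least 8 of 10 fibroblast markers were detected in every cluster, so these markers set no cluster apart. The fibroblast-like clusters made up 97.45% of cells in tube 1 (95% exact binomial interval 97.21% to 97.67%) and 90.92% in tube 2 (90.07% to 91.72%). A cluster of 2651 cells in tube 1 (14.43%) was led by the immediate early genes Dusp1, Junb, Egr1, Fos and Jun. The acute phase and metallothionein genes Lcn2, Saa3, Mt2, Mmp3 and Mt1 led another with 1528 cells (8.32%). In tube 2 a fibroblast-like cluster of 450 cells (9.42%) was led by the neutrophil chemokine genes Cxcl5, Cxcl2 and Cxcl1 with the matrix gene Tnc and the protease inhibitor Timp1, and a cluster of 537 cells (11.24%) by Pi16, Ly6a, Cxcl12, Dpt and Postn. Elastin (Eln) and the microfibril gene Mfap4 led a cluster of 2501 cells in tube 1 (13.61%) and a cluster of 512 cells in tube 2 (10.71%). Rare clusters were named for Schwann markers (45 and 17 cells, 0.245% and 0.356%), pericyte and smooth muscle markers (80 and 26 cells, 0.435% and 0.544%) and, in tube 2, keratinocyte markers (39 cells, 0.816%) and adipocyte markers (17 cells, 0.356%). Clusters left unnamed held 344 cells in tube 1 (1.87%) and 335 in tube 2 (7.01%), of which 312 and 83 were led by S100a8 and S100a9. In both of the latter the macrophage and dendritic, lymphocyte, neutrophil and mast cell lists passed. An unnamed cluster of 32 cells in tube 1 passed both the keratinocyte and the adipocyte list, led by Cfd, Lgals7, Krt17, Car3 and S100a3. Another 252 of the unnamed cells in tube 2 were led by Hp, Saa3, Postn, Col6a3 and Lgals1. That cluster had all 10 fibroblast markers and was unnamed because the tendon list passed without such genes leading it. It counts as outside the fibroblast-like clusters here and below. Prrx1 stood at 615.7 CPM in fibroblast-like clusters of tube 1 (609.1 to 622.3) against 641.7 (545.6 to 749.9) in the pericyte-like and 209.4 (132.7 to 314.2) in the Schwann-like cluster. In tube 2 it was 590.2 in fibroblast-like clusters.

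The genes called in bulk were then located in these clusters. Of the 18 genes lower in PPF at P30, 17 were detected in tube 1, of which 14 had their highest level outside fibroblast-like clusters, and 15 in tube 2, of which 13 did. Random lists of the same size and similar summed UMIs in the tube gave medians of 9 and 10 (percentiles 99.47 and 96.89, and 97.54 and 92.71 without members of any other cell type list). Their mean log2 level was 3.13 higher outside the fibroblast-like clusters than inside in tube 1 and 1.66 in tube 2. Of the 13 genes higher in PPF in the average, 12 were detected in each tube, and 0 and 2 of them had their highest level outside fibroblast-like clusters, where random lists of the same size and similar summed UMIs in the tube gave medians of 7 and 8. The 1 gene higher in PPF at P30, Plpp3, had its highest level inside them in both tubes.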

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

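The tests of explanations below were all written after the result they address was seen. Among 27 sets of values in groups of 4 to 6 libraries, 7 had a library far from the others. Chance alone puts such a library in about 1 in 20 independent sets, or 1.35 here. These sets are not independent, since they take related measures of the same libraries and some libraries of a group are closely alike. The 7 are therefore not separate surprises. In PNF E18.5 A the 50 most abundant genes took 53.48% of counts (next library of the group 25.14%), erythroid genes took 43.17% (next 2.929%), and Prrx1 stood at 104 CPM (next 46.69 CPM). Erythroid genes took 10.06% in PNF P1 A (next 0.933%) and 1.762% in PPF P30 A (next 0.283%). In PPF P30 A keratinocyte genes took 0.256% (next 0.062%), and in PPF P30 B mitochondrial transcripts took 10.5% (next 5.584%).

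Signals also appeared in data that no comparison used. Hashtags had 5005772 UMIs in tube 1 and 2674082 in tube 2, and 5.253% of bulk counts fell in transcripts matched to no gene.

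Most genes called in the lineage average, 92 of 105, were lower in PPF, and mast cell, keratinocyte, Schwann, muscle and myeloid markers such as Cpa3 and Krt15 were among them. Located in the single cells, 74 of 89 detected genes in tube 1 and 72 of 86 in tube 2 were highest outside fibroblast-like clusters, at percentiles 100 and 99.3 (mid-rank) of matched random lists (medians 52 and 63), and 54 of 65 and 52 of 62 were so without members of any other cell type list (percentiles 99.99 and 98.73). That could mean that PNF libraries hold more RNA of other skin cells, with list members such as Cpa3 (1209 ± 1133 CPM in PNF, 57.8 ± 142 CPM in PPF), Krt1 (1130 ± 1518 and 378 ± 908 CPM) and Lyz2 (404 ± 674 and 20.9 ± 24.9 CPM). The percentiles treat the called genes as independent, which genes of 1 cell type are not, so they are descriptive. The sort gate, which could decide this explanation, is not given. At P1 several keratinocyte genes had the higher mean in PPF, although libraries overlapped for Krt5 and Perp. That does not decide the explanation, because the keratinocyte share differed widely between libraries of a group (0.027% in PNF E18.5 B and 1.651% in PNF E18.5 D). Absorption of the difference by groups at 0 counts in the edgeR test cannot be the whole cause. Of the genes called by limma voom, which has no such limit, 82.5% were lower too. In both tests, though, the excess lies in genes with a group at 0 (82 of the 92 here, and 8 higher against 495 lower in limma voom). Of the called genes with a count in every group, 43.5% were lower in edgeR and 53.8% in limma voom. Whether limma voom treats groups at 0 unevenly in a way of its own was not tested. The 2 libraries rich in erythroid RNA cannot be the cause, since 86 of the 92 genes stayed past the threshold without them. The real grouping gave more calls than any other split tried, 50 against at most 9 with the similar pairs summed (105 and 29 with the pairs kept apart). Those splits still part libraries as alike as a summed pair, such as PNF E16.5 A and B (Pearson r of log2 CPM 0.965, against 0.929 for PNF P1 C and D). The labels do not say which libraries come from separate animals, so the splits do not exclude chance. A true lineage difference in these genes stays open and untested.

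Most genes called at E18.5 had 0 counts in both PPF E18.5 libraries. If each library had lost transcripts independently, 34.8 of 4948 well expressed genes would be at 0 in both, and 241 were. Other pairs of libraries of a group also exceeded their expectation, with 10 against 0.2 in PNF E16.5 and 17 against 0.4 in PPF P1. The excess is therefore not particular to this group. Independent loss at an equal rate among genes of similar level gives 34.8 and does not by itself account for the 241. Rates of loss that differ between such genes were not tried, so independent loss in that form is not excluded. A loss shared by both libraries before sequencing could also give such zeros. Of the genes counted in each of the other 22 libraries, 29 were at 0 in both, against 48 for the pair PPF P30 C and D. That does not decide it, because both libraries are the whole group. A true absence of transcripts such as Ly6a and Mfap5 in PPF at E18.5 stays open.

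Cartilage and bone genes fell from E16.5 to P30 in PPF, with a median log2 fold change of -5.25. Without replicate B of PPF E16.5 it was -0.10, and without replicate A -6.25. PPF E16.5 B had 4108 CPM of Col9a2 and 5208 CPM of Matn1, against 28.7 and 0 CPM in PPF E16.5 A, while PNF E16.5 A and B had 2504 and 1774 CPM of Col9a2. The fall in PPF could therefore come from RNA of cartilage or bone in 1 library, as read from genes chosen for naming after their values were seen, while the list had a median of -5.184 in PNF too, where both E16.5 libraries carry these genes, which goes against an origin particular to that library. Whether some PPF at E16.5 express these genes stays open, as no test here separates the explanations.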

How the results depend on the processing

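The alternatives without the 2 libraries rich in erythroid RNA, with similar pairs of libraries summed, with only genes counted in every group and without members of any other cell type list were chosen after the data were seen. The other alternatives were planned. Unless said otherwise the cause of a change was not tested.

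With DESeq2, PPF against PNF gave 89 genes at E16.5 (0 in edgeR), 1128 at E18.5 (28), 49 at P1 (0), 230 at P30 (19) and 844 in the average (105). PPF gave 652 from E16.5 to E18.5 (9) and 976 from E16.5 to P30 (113), and PNF 17 and 117 (0 and 0). The difference of changes gave 58 (0) and the interaction 172 (0). Limma voom with sample quality weights gave, in the same order, 116, 683, 293, 34 and 782, then 37 and 1141, 2350 and 459, 3 and 699.

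Without a filter on low counts there were 124 genes at E18.5, 144 at P30, 426 in the average, 22 and 181 in the PPF time course and 52 in the interaction. With RLE scaling there were 9 at P30. With upper quartile scaling there were 315 at P30, 14 from E16.5 to E18.5 in PPF and 8 in the interaction. A threshold on the fold (glmTreat) left 5 at P30, 47 in the average (0 higher), and 4 and 3 in the PPF time course, as its stricter hypothesis implies. It does not apply to the interaction.

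With libraries A and B only there were 0 at E18.5, 0 at P30, 17 in the average (0 higher) and 0 and 0 in the PPF time course. Only the groups compared gave 47 at E16.5, 0 at E18.5, 1 at P30 and 0 from E16.5 to E18.5 in PPF, and cannot be run for the average or the interaction. Without the 2 libraries rich in erythroid RNA there were 218 at E18.5, 6 at P30, 320 in the average, 164 and 411 in the PPF time course, 13 from E16.5 to P30 in PNF and 39 in the interaction. With similar pairs summed there were 6 at E18.5, 1 at P30, 50 in the average (0 higher, where the fit of all libraries has 13) and 1 and 0 in the PPF time course. With only genes counted in every group (11243 tested) there were 0 at E18.5, 0 at P30, 1 in the average and 0 from E16.5 to E18.5 in PPF, while there were 120 from E16.5 to P30 in PPF, 96 of them among the 113. Of the 28 genes at E18.5, 23 had 0 counts in PPF and so were left out of that fit, and why the others lost their call was not tested.

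A replicate block pairing libraries by letter gave 0 genes at E18.5, at P30 and in the average, with 4 residual degrees of freedom. No sign of pairing by letter was seen, as the 8 same-letter correlations of deviations lay between -0.027 and 0.079. In groups of 2 libraries the deviations mirror each other, so these are not 8 separate checks. They cannot show that same-letter libraries come from different animals. The block could not be run within a lineage.

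With 1 library left out, the lone library of a group is assumed to vary like the other groups. Counts ranged from 2 to 50 at E18.5, from 3 to 2687 at P30, from 2 to 1480 in the average, from 0 to 3 and from 0 to 153 in the PPF time course, from 0 to 1693 from E16.5 to P30 in PNF, from 0 to 1714 in the difference of changes and from 0 to 1453 in the interaction.

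Camera calls on gene lists were mostly lost with an estimated correlation: 20 to 1 at E16.5, 15 to 0 at E18.5, 12 to 0 at P1, 17 to 0 at P30, 23 to 1 in the average, 8 to 0 and 14 to 1 in the PPF time course, 20 to 0 and 14 to 0 in that of PNF and 2 to 0 in the difference. With fry they were 1, 8, 0, 2, 12, 0, 8, 0, 3 and 0. Among genes of at least 10 CPM, Pearson r was 0.464 between E16.5 and E18.5 (0.298 over all genes) and 0.424 between E16.5 and P30 (0.265). Spearman rho was 0.113 (0.158 over all genes) and 0.297 (0.213) for these pairs, and 0.044 (0.091) between E18.5 and P30.

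Fibroblast-like cells were 96.55% and 95.78% of tubes 1 and 2 with at least 200 genes per cell, and 97.06% and 95.90% with up to 20% mitochondrial UMIs. In the main setting they were 97.45% and 90.92%. The tube 2 shares of both alternatives thus lay above the binomial interval of the main setting, which ended at 91.72%. That interval covers the sampling of cells only, and not how a filter or the naming of clusters moves the share. Genes called higher in PNF at P30 had a difference outside minus inside fibroblast-like clusters of 2.375 and 0.863 without members of the proliferation, erythroid, immune, keratinocyte, endothelial and muscle lists, and 2.222 and 0.752 without members of any other cell type list (3.129 and 1.662 with all of them). With all members, the tube 2 difference rose to 2.754 with at least 200 genes per cell and to 2.700 with up to 20% mitochondrial UMIs. The tube 1 values there were 3.306 and 2.854. In tube 2 the difference for genes higher in PPF was -0.708 for the average and -1.403 for P30.

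Single genes changed direction rarely. Many were named because their libraries do not overlap between groups, so that a change of direction was unlikely from the start. The 136 entries counted here are pairs of a named gene and a comparison, so a gene can count several times. Across the fits that left out 1 library they gave 1442 values. Of these 899 kept direction and side of the threshold, 525 kept direction only, 15 came past the threshold and 3 changed direction. In the other settings these were 1132, 391, 82 and 4 of 1609. The log2 fold change of Prrx1, P30 versus E16.5 in PNF, was -0.29 and became 0.11 with DESeq2, 0.11 with RLE, 0.15 with voom and 0.71 without the 2 libraries rich in erythroid RNA. With 1 library left out it ranged from -11.19 without PNF P30 replicate B to 0.71 without PNF P30 replicate A. That of Lor, PPF versus PNF at P1, ranged from -0.67 without PPF P1 replicate A to 5.91 without PPF P1 replicate B. That of Krt79, PPF versus PNF at P30, ranged from -9.91 without PPF P30 replicate B to 5.99 without PNF P30 replicate B.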

Other observations

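In the lineage average no gene of the Wnt and hedgehog lists passed the edgeR test. Rspo4, a Wnt agonist gene, had 294 CPM in PPF and 6.58 CPM in PNF (adjusted p = 0.0588) and the hedgehog target Gli1 108 and 43.2 CPM (adjusted p = 0.108). In the Wnt list 0 of 31 and in the hedgehog list 0 of 11 passed, and 1 gene of each was higher when adjusted over the list alone. Camera ranked both upward (adjusted p = 0.000493 and 0.00167), and these were adjusted p = 0.262 and adjusted p = 0.283 with an estimated correlation. By fry, which asks whether a list moves one way, they were adjusted p = 0.131 and 0.143, so no shift of either list is shown.

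The sex of the animals is not given in the sources used here. Xist stood at 398 CPM in PPF and 83.5 CPM in PNF over 12 libraries each (adjusted p = 0.724), and of the 5 sex-linked genes tested 0 passed. Adjusted over the list alone, 3 of the 5 were lower in PPF at E18.5 and 3 in the average, where camera gave adjusted p = 0.0142, and adjusted p = 0.186 with an estimated correlation, and fry adjusted p = 0.0359. At E18.5 Ddx3y had 0 counts in both PPF libraries and 1.11, 179, 127 and 147 CPM in PNF A to D, while Xist had 751 and 863 CPM in PPF and 498, 0, 36.2 and 36.1 CPM in PNF. Lineage and sex are therefore not fully separated at that age.

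A hashtag was taken as clear where its log count, centred per cell, lay over 1.5 above the median of that hashtag. No other cutoff was tried. In tube 1, 27.43% of cells had 1 clear hashtag and 71.3% had none, and in tube 2 these were 24.25% and 74.79%. Cells without a clear hashtag are not thereby unlabelled, since hashtag 4 had medians of 54 and 79 UMIs per cell in tubes 1 and 2. Another 1.263% and 0.9625% had 2 hashtags and were kept, although 2 hashtags are a mark of doublets. Nearly all hashtag UMIs belonged to 6 hashtags, while 8 samples are described as pooled.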
